A study of Mus musculus with 42 samples.

How the data were processed

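RNA was sequenced from the lung and the liver of 21 mice, giving 42 libraries. Per the labels, each mouse received either ethanol or a pair-fed control diet and was sampled 9 h, 24 h or 14 d after a single binge, with 4 ethanol and 3 pair-fed mice at each time. The design text states that both tissues came from the same mice and that the 14 d mice went on drinking after the binge. The sample titles of the 14 d mice carry an extra tag in both diets, whose meaning the labels do not give. It stands in both arms of the 14 d comparison, so it does not separate the diets, but it does set the 14 d mice apart from those of the other times.

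Per the labels' protocols, the lower right lung lobe was placed in a stabilising solution, RNA was extracted on columns, polyadenylated RNA was enriched on oligo(dT) beads, and libraries were sequenced as read pairs. The protocol field describes the lung lobe for the liver libraries too, so the sampled part of the liver is not given in the sources used here. No batch, date or sequencing lane is given either. Per the submitters' processing notes, the tool kallisto and the genome build GRCm39 were used. The kallisto version and the annotation are not given in the sources used here. The reference genome at hand was of an earlier build, so genes are named by the symbols in the deposited tables and no coordinates are given.

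The deposited tables hold, per gene and library, estimated counts and transcript abundances (TPM) as the authors made them with kallisto, already summed to genes. They cover 21709 genes in lung and 21693 in liver. The estimated counts need not be whole, because kallisto shares a read among the transcripts it fits, and members of near-identical families can exchange reads. Families such as Mup, Cyp2a, Cyp2b, Cyp2c, Gsta, H2-Q, Orm, Saa and the globins are therefore uncertain gene by gene. The TPM values of the deposited tables sum to between 832666 and 890371 per library. The 84 per-library files were compared with the tables of the whole series and 0 differed. A further 8 columns of the tables match no sample of the series and were not used.

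Estimated counts were rounded to whole numbers and summed to 14.6 to 19.2 M (M, mega) per lung library (median 16.1) and 16.0 to 24.5 M per liver library (median 21.4). With at least 1 count required, 17278 to 17702 genes were detected per lung library and 15749 to 16635 per liver library. Mitochondrially encoded transcripts took 2.49 to 3.85% of lung counts and 5.2 to 8.11% of liver counts. Libraries of the same group were compared pair by pair. The chi-square statistic per gene over the 27 pairs of each tissue was 3.55 to 21.3 in lung and 11.3 to 114.9 in liver, well above the sampling noise of a library sequenced again, so each library was counted as 1 mouse. Within a tissue, each label names a separate mouse.

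Differences were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling factors, the filterByExpr filter on the 6 groups of a tissue, a quasi-likelihood fit with robust dispersion moderation in its current, non-legacy form, and quasi-likelihood F-tests. All 21 libraries of a tissue entered a single fit with a coefficient per diet and time, so that all groups share an estimate of the spread. The spread was not equal among times. In lung, the chi-square statistic per gene of same-group pairs was 12.45 to 21.3 at 9 h and 3.55 to 12.06 at 14 d. A shared estimate can therefore add calls at 9 h and remove calls at 14 d, so counts of changed genes are not strictly comparable between times. Adjusted p-values are Benjamini-Hochberg values over all genes tested in that comparison, with a threshold of 0.05. TMM factors ran from 0.966 to 1.03 in lung and from 0.894 to 1.15 in liver. Standard errors of log2 fold changes were obtained from the F statistics. The same fits tested whether the ethanol effect differed among the 3 times and whether the pair-fed mice differed among times. A fit over all 42 libraries, with TMM factors computed within each tissue and genes passing the filter in both, tested whether the ethanol effect differed between liver and lung. CPM values (counts over the scaled library size in M) are those of this scaling, given as mean ± SD.

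Lung and liver share mouse numbers, and the design text states that they came from the same mice, so the numbers pair the tissues. Over 8624 genes, the deviations of the lung and the liver of the same mouse from their group means correlated with r between -0.0806 and 0.221 (median 0.121, above 0.1 in 12 of the 21 mice). The median was -0.0444 for different mice of the same group. Deviations from a group mean sum to 0, so values above 0 for the same mouse push those for different mice below 0. The latter are therefore no separate control. These are correlations across genes, which are not independent replicates. The difference between tissues was fitted without the mouse as a block, and the blocked fit was run as an alternative.

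A set of 52 gene lists was written from textbook knowledge, covering metabolic, stress and immune pathways, the cell types of lung and liver, and other tissues. They were tested with camera (limma 3.58.1, on voom values, with a preset correlation of 0.01 between genes) and adjusted over the lists tested in each comparison, which were 50 in lung and 49 in liver after lists with fewer than 5 measured genes were left out. Of the list calls made with the preset correlation, cell division in lung at 24 h was the only call that held when the correlation was estimated. For each list the number of genes past the threshold is given over all genes tested and also adjusted over the list alone.

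Genes named below follow a fixed rule. It takes up to 8 higher and 8 lower genes of largest log2 fold change among those past the threshold, with a mean CPM of at least 5 in the higher group and no overlap between the diets, leaving out unnamed gene models and immunoglobulin and T cell receptor segments. It adds up to 3 genes per list of smallest p past the threshold, and 21 genes of ethanol, lipid, glucose, clock, inflammatory and alveolar biology whatever their result. Tests among times and between tissues name up to 8 genes of smallest p, and a comparison with fewer than 10 calls may name them all. The design, lists, rule and the alternative fits named next were fixed before the data were examined.

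The steps were tested on simulated data, with counts drawn from the real means and library sizes, a dispersion of 0.03 for every gene, and known genes changed. At a true 2-fold change, the edgeR test recovered 89.4, 78.8 and 82.1% of the changed genes of the simulated lung comparisons at 9 h, 24 h and 14 d, among 15470 genes. It recovered 80.0, 86.4 and 82.1% of those of liver, among 13505 genes. At 1.5-fold, recovery was 14.9 to 24.2%. The simulation changed 200 genes per comparison, where 2671 were called in the real lungs at 9 h, and gave every gene the same dispersion. Recovery in the real data can therefore differ.

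The alternatives fixed at the start were DESeq2 1.42.0, RLE scaling, no filter on low counts, a filter of CPM 1 in 3 libraries, the legacy dispersion fit, voom with sample quality weights, limma on log2(TPM + 1), fits of only the libraries compared, each mouse left out in turn, and list tests with an estimated correlation or with fry. Another 2 were chosen after the data were seen: lung counts with an estimated liver share subtracted, and the 9 h lungs without mice 4 and 5. The liver share of a lung library was estimated as the median, over the 19 hepatocyte markers, of the lung level less its 14 d pair-fed mean, divided by the level in the liver library that the 9 h lungs resembled most, that of ethanol mouse 15 at 24 h. It was checked on 191 other genes at least 500 times as abundant in liver as in 14 d pair-fed lungs, at a liver CPM of at least 50. Because the share rests on the hepatocyte markers, the end of their list call after subtraction follows in part from the construction. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.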

Results

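Messenger RNA was measured in the lung and the liver of 21 mice given ethanol or a pair-fed control diet, at 9 h and 24 h after a single binge and again at 14 d, when drinking had continued. Each time had 4 ethanol and 3 pair-fed mice. After the low-count filter, 15623 genes were tested in lung and 13752 in liver. Lung libraries held 14.6 to 19.2 M counts and liver libraries 16.0 to 24.5 M (M, mega). Values after ± are SD for CPM and shares and SE for log2 fold changes, which are ethanol against pair-fed. Ethanol groups are n = 4 and pair-fed groups n = 3 throughout. The comparisons ask what the ethanol diet and binge changed in lung and liver transcripts, how this differed with time, and how far the lung followed the liver of the same mice.

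**Figure D1:**
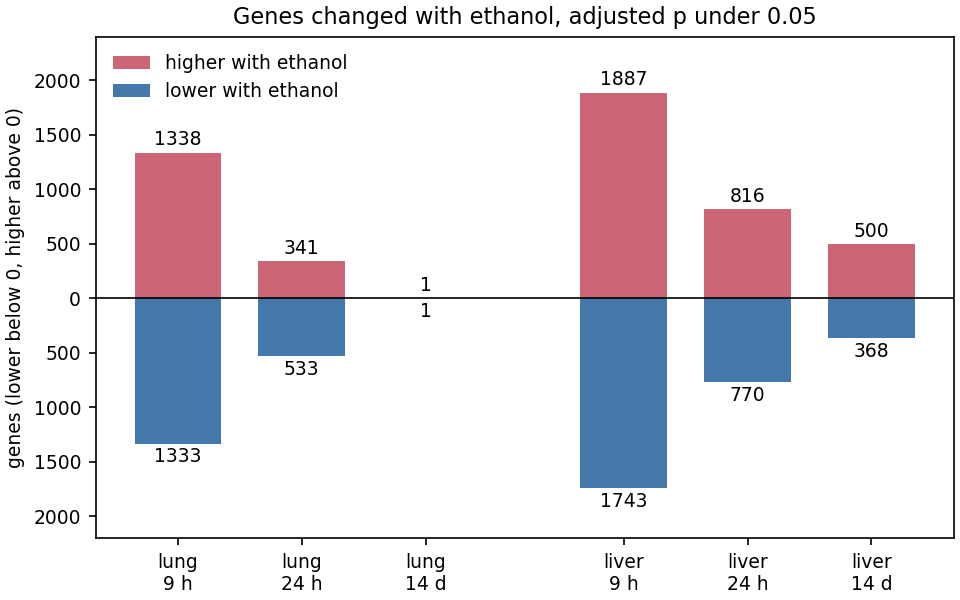
Genes higher (red, above 0) and lower (blue, below 0) with ethanol at an edgeR adjusted p under 0.05, for lung and liver at 9 h, 24 h and 14 d. Counts run from 1887 higher and 1743 lower in liver at 9 h to 1 higher and 1 lower in lung at 14 d.

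Transcripts of cytotoxic lymphocytes and of monocytes were lower in ethanol lungs 9 h after the binge. Gzma, a protease of cytotoxic granules, measured 3.43 ± 1.95 CPM with ethanol (n = 4) and 22.1 ± 3.75 CPM in pair-fed lungs (n = 3), a log2 fold change of -2.68 ± 0.29 (edgeR adjusted p 8.7e-06). The pore-forming protein Prf1 (-2.06 ± 0.27), the NK receptor Klra8 (-2.63 ± 0.29), uncertain among the Klra copies, and the sphingosine phosphate receptor S1pr5 (-2.93 ± 0.35), which guides NK cells out of tissues, fell too. Of 14 NK cell markers, 14 fell, and 14 also when adjusted over the list alone (camera adjusted p 2.94e-15, adjusted p = 0.221 with an estimated correlation). Of 18 T cell markers, 8 fell and 10 did not pass, and 14 were lower adjusted over the list alone (camera adjusted p 7.81e-06, adjusted p = 0.478 with an estimated correlation). Without mice 4 and 5, 12 NK cell markers and 0 T cell markers were lower.

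Among monocyte and interstitial macrophage markers, 9 of 17 fell, 1 rose and 7 did not pass, and the counts were the same adjusted over the list alone (camera adjusted p 6.26e-05, adjusted p = 0.478 with an estimated correlation). The growth factor receptor Csf1r fell from 191 ± 14.9 to 125 ± 3.57 CPM (log2 fold change -0.61 ± 0.06, edgeR adjusted p 1.15e-06). The adhesion receptor Adgre4 had a log2 fold change of -3.56 ± 0.44 (edgeR adjusted p 3.61e-05) and Cd300e, a monocyte receptor, of -2.15 ± 0.28. The immediate early gene Nr4a1, a nuclear receptor, fell from 289 ± 110 to 77.3 ± 28.8 CPM (edgeR adjusted p 0.00881). Antigen presentation genes moved the same way. Of 10 MHC class II genes, 8 fell, and 10 adjusted over the list alone (camera adjusted p 1.59e-07, adjusted p = 0.362 with an estimated correlation), with H2-Ab1 at -0.84 ± 0.12. Of 37 interferon-stimulated genes, 13 fell, and 17 adjusted over the list alone (camera adjusted p 1.52e-06, adjusted p = 0.478 with an estimated correlation). An example was Gbp2, a guanylate-binding protein (-0.90 ± 0.10). Of 18 ER chaperones, 8 fell, and 10 adjusted over the list alone (camera adjusted p 0.000735, adjusted p = 0.478 with an estimated correlation), among them Calr (-0.44 ± 0.09) and Pdia6 (-0.41 ± 0.07). Without mice 4 and 5, 4 ER chaperones were lower.

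Genes of lipid use and of the stress response rose. Plin2, which coats lipid droplets, went from 110 ± 7.21 to 166 ± 13.5 CPM (log2 fold change 0.60 ± 0.07, edgeR adjusted p 1.73e-05). The acyl-CoA thioesterase Acot2 (0.72 ± 0.11) and the isomerase Eci2 (0.58 ± 0.09) rose with it. Of 32 fatty acid oxidation genes and PPARA targets, 14 rose and 18 did not pass, and 18 were higher adjusted over the list alone (camera adjusted p 5.36e-07, adjusted p = 0.478 with an estimated correlation). The stress transcription factor Atf5 rose by 0.81 ± 0.10 on the log2 scale and the pseudokinase Trib3 by 0.83 ± 0.18. In the integrated stress response list, 6 of 15 rose and 1 fell, or 6 and 2 adjusted over the list alone (camera adjusted p 0.00712, adjusted p = 0.478 with an estimated correlation), and 3 rose and 0 fell without mice 4 and 5. Calca, which encodes calcitonin and a vasoactive peptide (2.36 ± 0.30), and the adenosine receptor Adora1 (2.03 ± 0.29) were among the genes that rose most.

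Liver transcripts were present in the 9 h lung libraries. Their estimated share was 0.870 ± 0.661% with ethanol (n = 4) and 0.265 ± 0.120% in pair-fed lungs (n = 3; exact two-sided permutation p 0.257), and it reached 1.37% in mouse 4 and 1.51% in mouse 5. Of 19 hepatocyte markers, 16 rose in ethanol lungs, and 19 adjusted over the list alone (camera adjusted p 7.81e-06, adjusted p = 0.531 with an estimated correlation), and 0 without mice 4 and 5. With the share subtracted, 5 of the 13 still tested were higher, at a median log2 fold change of 1.42 (camera adjusted p 0.279). The share is a median over these same markers, so some keep a remainder by construction. Too much taken from pair-fed lungs would raise the fold change too. These markers therefore cannot show whether the subtraction was complete. Of the 1338 genes called higher, 149 were at least 100 times as abundant in liver as in 14 d pair-fed lung, against 0 of the 1333 called lower. Several higher groups also lost calls with the share subtracted or without mice 4 and 5. Without these mice, calls also fell for T cell markers, which were lower (8 to 0), and rose for higher neutrophil markers (5 to 13). A fall without mice 4 and 5 therefore does not by itself mark liver transcripts. Acute phase genes numbered 13 higher of 24, or 15 adjusted over the list alone (camera adjusted p 1.81e-06, adjusted p = 0.327 with an estimated correlation), 7 with the liver share subtracted and 5 without mice 4 and 5. Saa1, a serum amyloid protein, had a log2 fold change of 2.15 ± 0.43, and 3.37 with the share subtracted. The subtraction rests on a single liver library with Saa1 at 655 CPM, where pair-fed livers had 23.8 to 83.9 CPM, which can take too much from pair-fed lungs and so favours this call and the count of 7. The apolipoprotein Apoa4 (2.14 ± 0.48) and the protease inhibitor Mug1 (2.15 ± 0.51) no longer reached the low-count filter with the share subtracted. Fatty acid oxidation genes numbered 10 higher with the share subtracted and 6 without mice 4 and 5. Bile acid genes numbered 10 of 15 higher, or 11 adjusted over the list alone (camera adjusted p 0.000163, adjusted p = 0.478 with an estimated correlation), 3 with the share subtracted and 3 without mice 4 and 5. Targets of the xenobiotic receptors CAR and PXR numbered 8 of 15 higher, or 8 adjusted over the list alone (camera adjusted p 0.000703, adjusted p = 0.478 with an estimated correlation), 3 with the share subtracted and 3 without mice 4 and 5. All NK cell markers remained lower with the share subtracted, and 8 MHC class II and 14 interferon-stimulated genes were lower.

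**Figure D2:**
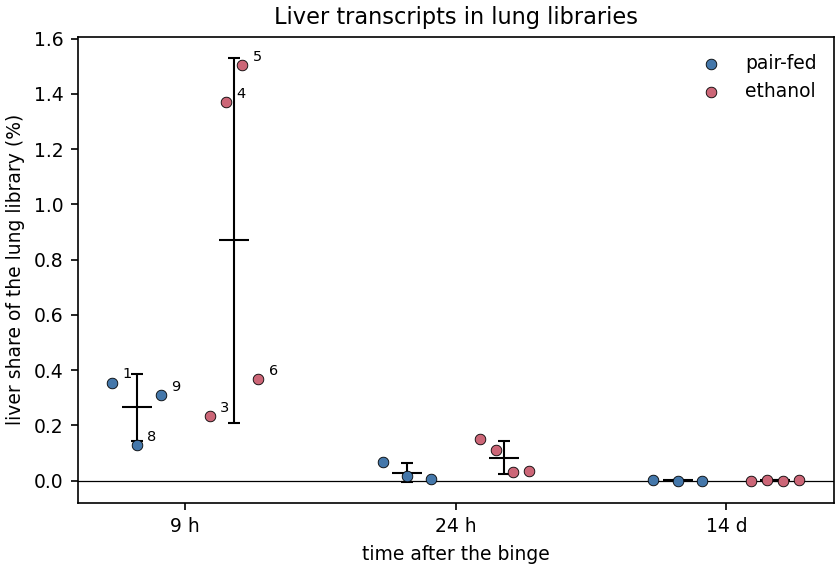
Estimated liver share (%) of each lung library by time and diet, with the mean and SD of each group and mouse numbers at 9 h. Ethanol mice 4 and 5 lie at 1.37 and 1.51%, and every 14 d lung lies at 0.00417% or below.

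Neutrophil markers at 9 h differed widely between mice. The collagenase Mmp8 measured 61.0 ± 83.7 CPM with ethanol and 5.37 ± 0.26 CPM in pair-fed lungs (log2 fold change 3.50 ± 0.83, edgeR adjusted p 0.00956). Of 17 neutrophil markers, 5 rose and 1 fell, and the counts were the same adjusted over the list alone (camera adjusted p 0.01, adjusted p = 0.743 with an estimated correlation). The list lost its call without mouse 6 or mouse 8, with a highest camera adjusted p of 0.157, and 13 markers were higher without mice 4 and 5. The iron-binding protein Lcn2 rose (1.05 ± 0.22, edgeR adjusted p 0.0044). Among the genes reported whatever their result, the scavenger receptor Marco (0.53 ± 0.18, edgeR adjusted p 0.0481) and the clock output gene Dbp (-1.02 ± 0.32, edgeR adjusted p 0.0399) passed. Marco lost its call without mouse 1, 4, 5 or 8 (edgeR adjusted p 0.188, 0.157, 0.0706 and 0.0996) and Dbp without mouse 1, 3, 5 or 6 (edgeR adjusted p 0.339, 0.0729, 0.0749 and 0.102). The other 17 of these genes measured, Adh1, Aldh1a1, Aldh2, Cat, Chil3, Cyp2e1, Fasn, Fkbp5, Hk2, Hmox1, Il1b, Ldha, Per1, Pkm, Scd1, Sftpc and Tnf, did not pass, with log2 fold changes from -0.84 (Tnf) to 1.28 (Fkbp5) and edgeR adjusted p of 0.109 or above. In all, 2671 of 15623 lung genes changed at 9 h, 1338 higher and 1333 lower, of which 260 and 200 changed at least 2-fold. The diets did not overlap for 21.9% of genes, where chance gives 5.71%. The count was 1474 without mouse 1, 1561 without mice 4 and 5, 1488 with voom and 768 with only the 7 lungs of that time.

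At 24 h, interferon-stimulated, cell division, NK cell and erythroid transcripts were lower in ethanol lungs. The antiviral gene Rsad2 fell from 14.4 ± 5.85 to 5.32 ± 1.06 CPM (log2 fold change -1.42 ± 0.21, edgeR adjusted p 0.000905; ethanol n = 4, pair-fed n = 3). The interferon-inducible GTPases Gbp6 (-1.31 ± 0.20) and Igtp (-0.88 ± 0.11) fell too. Of 37 interferon-stimulated genes, 22 fell, and 29 adjusted over the list alone (camera adjusted p 1.76e-21, adjusted p = 0.0959 with an estimated correlation). Of 30 cell division genes, 17 fell, and 22 adjusted over the list alone (camera adjusted p 1.1e-15). This list kept its call with an estimated correlation (adjusted p = 0.00156). Topoisomerase Top2a (-1.26 ± 0.18) and the proliferation marker Mki67 (-1.17 ± 0.16) were examples. Of 14 NK cell markers, 12 fell, and 14 adjusted over the list alone (camera adjusted p 4.75e-13, adjusted p = 0.106 with an estimated correlation), with Klra8 at -1.16 ± 0.20. Of 10 MHC class II genes, 7 fell, and 10 adjusted over the list alone (camera adjusted p 2.57e-11, adjusted p = 0.141 with an estimated correlation), with H2-Eb1 at -0.96 ± 0.12. Of 14 MHC class I genes, 8 fell, and 10 adjusted over the list alone (camera adjusted p 5.84e-10, adjusted p = 0.186 with an estimated correlation), with the peptide transporter Tap1 at -0.55 ± 0.09. Other lymphocyte lists were called lower too. Of 15 B cell markers, 0 passed in edgeR (median -0.71, camera adjusted p 3.48e-06). Of 18 T cell markers, 1 fell, and 4 adjusted over the list alone (median -0.32, camera adjusted p 3.52e-05). With an estimated correlation both had adjusted p = 0.426.

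Erythroid transcripts and the platelet chemokine Ppbp were lower as well. Ppbp fell from 28.5 ± 5.40 to 7.0 ± 0.801 CPM (log2 fold change -2.03 ± 0.17, edgeR adjusted p 2.33e-06). Of 10 erythroid markers, 8 fell, and 8 adjusted over the list alone (camera adjusted p 2.18e-12, adjusted p = 0.0959 with an estimated correlation). The haem synthesis enzyme Alas2 had -1.01 ± 0.14 and the globin Hbb-bt -1.06 ± 0.14, the latter uncertain because globin copies can exchange reads. Globin transcripts took 0.387 ± 0.0466% of lung counts with ethanol (n = 4) and 0.708 ± 0.104% in pair-fed lungs (n = 3).

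Some smooth muscle markers and chaperones rose at 24 h. The heat shock protein Hspb1 went from 138 ± 14.9 to 275 ± 41.4 CPM (log2 fold change 1.00 ± 0.14, edgeR adjusted p 0.000818). Tagln, an actin-binding protein of smooth muscle, rose by 0.69 ± 0.12 on the log2 scale, and the muscle ankyrin protein Ankrd1 by 1.15 ± 0.18. Of 10 smooth muscle markers, 5 rose, and 9 adjusted over the list alone (camera adjusted p 2.65e-09, adjusted p = 0.182 with an estimated correlation). Of 18 ER chaperones, 8 rose, and 12 adjusted over the list alone (camera adjusted p 1.89e-07, adjusted p = 0.306 with an estimated correlation), with Calr at 0.49 ± 0.09. Of 14 heat shock genes, 4 rose, and 7 adjusted over the list alone (camera adjusted p 6.51e-07, adjusted p = 0.418 with an estimated correlation). The surfactant proteins Sftpa1 (0.44 ± 0.07) and Sftpd (0.51 ± 0.09) rose. Of 13 alveolar type 2 markers, 4 rose and 1 fell, or 6 and 1 adjusted over the list alone (camera adjusted p 0.00892, adjusted p = 0.469 with an estimated correlation), and the list call ended without mouse 11 (camera adjusted p 0.0519). Of 18 ciliated cell markers, 2 rose, and 9 adjusted over the list alone (camera adjusted p 5.95e-06, adjusted p = 0.426 with an estimated correlation). Other tissue parts moved with smooth muscle as lists. Of 21 fibroblast and matrix genes, 2 rose, and 7 rose and 2 fell adjusted over the list alone (camera adjusted p 0.000176, adjusted p = 0.426 with an estimated correlation). Of 13 club and secretory cell markers, 0 passed in edgeR (median 0.71, camera adjusted p 0.000176, adjusted p = 0.426 with an estimated correlation). Of 11 adipocyte markers, 0 passed (median 1.23, camera adjusted p 0.00454, adjusted p = 0.505 with an estimated correlation), and the list call ended without mouse 12 (camera adjusted p 0.0866). Of 13 cardiac muscle markers, 0 passed (median 0.41, camera adjusted p 0.0276, adjusted p = 0.638 with an estimated correlation), and the call ended without mouse 10, 11, 12 or 16, with a highest camera adjusted p of 0.386. The liver share of the lungs was 0.0828 ± 0.0594% with ethanol and 0.0294 ± 0.0330% in pair-fed lungs (exact two-sided permutation p 0.257). Hepatocyte markers were called higher as a list, though 0 of 19 passed in edgeR (median 1.14, camera adjusted p 0.0281, adjusted p = 0.738 with an estimated correlation). That call ended with the share subtracted (camera adjusted p 0.815), in part by construction.

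Among the genes reported whatever their result, Marco (0.84 ± 0.18, edgeR adjusted p 0.0114) and Plin2 (0.32 ± 0.07, edgeR adjusted p 0.0144) passed in lung at 24 h. Both lost the call without mouse 12 (edgeR adjusted p 0.0812 and 0.0953). Lcn2 (1.15 ± 0.23) lost it without mouse 12 too (edgeR adjusted p 0.0687). The other 18 genes of that set measured did not pass, with log2 fold changes from -0.09 (Fkbp5) to 1.56 (Cyp2e1) and edgeR adjusted p of 0.0967 or above. In all, 874 lung genes changed at 24 h, 341 higher and 533 lower, of which 31 and 74 changed at least 2-fold. The diets did not overlap for 20.2% of genes, where chance gives 5.71%. The count was 509 without mouse 11, 192 without mouse 12, 416 without mouse 14 and 321 without mouse 16. It was 1333 with voom and 483 on log2(TPM + 1).

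Few genes passed the threshold in lung at 14 d. Acap2, a GTPase-activating protein, measured 89.9 ± 19.4 CPM with ethanol (n = 4) and 27.1 ± 7.32 CPM in pair-fed lungs (n = 3), a log2 fold change of 1.73 ± 0.24 (edgeR adjusted p 0.0231). Ppbp fell from 28.8 ± 4.15 to 14.3 ± 1.67 CPM (log2 fold change -1.01 ± 0.16, edgeR adjusted p 0.0231). They were the 2 genes that passed of 15623, with 1532 at an unadjusted p under 0.05, and the diets did not overlap for 13.9% of genes, where chance gives 5.71%. Acap2 lost its call without mouse 20, 21, 25, 27 or 28 (edgeR adjusted p 0.139, 0.16, 0.0679, 0.0572 and 0.098). Ppbp lost it without mouse 19, 20, 21, 25, 27 or 28 (edgeR adjusted p 0.125, 0.231, 0.0726, 0.121, 0.0572 and 0.098). The count was 1 without mouse 19, 0 without mouse 20, 21, 25, 27 or 28, and 23 without mouse 26. DESeq2 called 82 genes (50 higher, 32 lower), voom 202, the fit of only the 7 lungs of that time 135, and limma on log2(TPM + 1) 1, Acap2. None of the 20 genes reported whatever their result passed, with log2 fold changes from -0.43 (Scd1) to 1.80 (Fkbp5) and edgeR adjusted p of 0.194 or above. Of 18 glucocorticoid targets, 0 passed over all genes and 4 were higher adjusted over the list alone (camera adjusted p 7.19e-10, adjusted p = 0.882 with an estimated correlation). Of 19 circadian clock genes, 0 passed over all genes, and 12 were higher and 3 lower adjusted over the list alone (camera adjusted p 1.13e-05, adjusted p = 0.58 with an estimated correlation). Of 15 B cell markers, 0 passed in edgeR, over all genes or the list alone, with a median log2 fold change of -0.85 (camera adjusted p 3.71e-10, adjusted p = 0.882 with an estimated correlation). T cell markers (median -0.28, camera adjusted p 0.000313), MHC class II genes (median -0.19, camera adjusted p 0.000626) and interferon-stimulated genes (median -0.12, camera adjusted p 0.00123) were also called lower as lists, with adjusted p = 0.985 with an estimated correlation for each. The MHC class II call ended without mouse 27 (camera adjusted p 0.0887). Camera called 13 lists in lung at 14 d, 7 higher and 6 lower, of which 0 held with an estimated correlation.

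**Figure D3:**
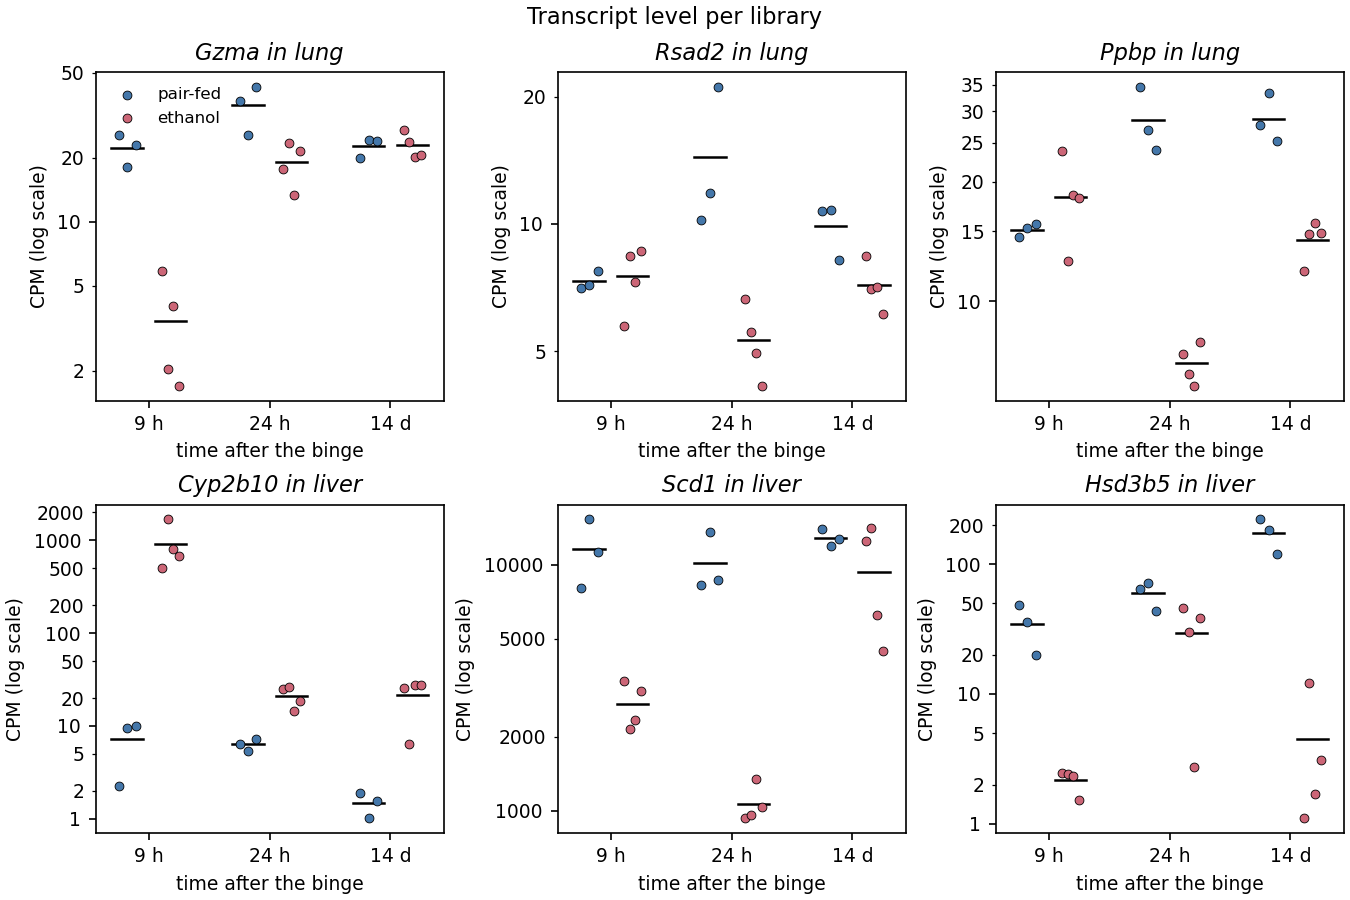
CPM per library (log axes) of 6 genes by time, with pair-fed mice in blue, ethanol mice in red and the group mean as a line. Gzma at 9 h and Ppbp at 24 h in lung, and Cyp2b10 at 9 h and Scd1 at 24 h in liver, do not overlap between diets.

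In liver at 9 h, drug-metabolising and oxidative stress genes rose while sterol and fatty acid synthesis genes fell. Cyp2b10, the classic target of the receptor CAR, went from 7.22 ± 4.28 CPM in pair-fed livers (n = 3) to 913 ± 522 CPM with ethanol (n = 4), a log2 fold change of 6.99 ± 0.66 (edgeR adjusted p 3.55e-06). Of 19 CAR and PXR targets, 14 rose, and 15 adjusted over the list alone (camera adjusted p 1.96e-07, adjusted p = 0.705 with an estimated correlation). Cyp2a5 rose by 2.21 ± 0.27 on the log2 scale and Gstm3 by 4.49 ± 0.73, each uncertain within its family. The haem-degrading enzyme Hmox1 rose from 12.9 ± 3.32 to 212 ± 218 CPM (log2 fold change 4.04 ± 0.69, edgeR adjusted p 0.000494). Of 25 NRF2 and glutathione genes, 16 rose and 1 fell, or 16 and 2 adjusted over the list alone (camera adjusted p 6.1e-06, adjusted p = 0.706 with an estimated correlation), with the quinone reductase Nqo1 at 1.67 ± 0.19 and the sulfiredoxin Srxn1 at 2.34 ± 0.27. The metallothionein Mt2 had 4.50 ± 1.23 (edgeR adjusted p 0.0134) and lost its call without mouse 1 (edgeR adjusted p 0.0543).

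Of 22 cholesterol synthesis genes, 18 fell, and 18 adjusted over the list alone (camera adjusted p 3.32e-11, adjusted p = 0.706 with an estimated correlation). Insig1, which holds the sterol sensor in the ER, fell from 369 ± 37.8 to 70.5 ± 20.1 CPM (log2 fold change -2.39 ± 0.28, edgeR adjusted p 1.2e-05). Of 18 fatty acid synthesis genes, 12 fell, and 12 adjusted over the list alone (camera adjusted p 1.15e-06, adjusted p = 0.706 with an estimated correlation). The desaturases Scd1 (-2.08 ± 0.32) and Fads2 (-2.04 ± 0.19) and the transcription factor Srebf1 (-1.77 ± 0.27) fell. Fatty acid synthase Fasn had -1.26 ± 0.34 (edgeR adjusted p 0.0111) and lost its call without mouse 8 (edgeR adjusted p 0.0619). Of 29 cell division genes, 12 fell, and 17 adjusted over the list alone (camera adjusted p 2.73e-05, adjusted p = 0.909 with an estimated correlation). The replication helicase subunits Mcm5 (-3.66 ± 0.53) and Mcm6 (-2.93 ± 0.46) were among the genes that fell most, with Ppp1r3g, which targets a phosphatase to glycogen (-4.61 ± 0.94), and the steroid enzyme Hsd3b5 (-4.00 ± 0.81).

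Acute phase and stress genes rose in liver at 9 h. Lcn2 went from 7.86 ± 1.24 to 378 ± 404 CPM (log2 fold change 5.59 ± 1.08, edgeR adjusted p 0.0014), and Orm3 rose by 4.16 ± 0.54 on the log2 scale, uncertain among the Orm copies. Of 26 acute phase genes, 13 rose and 1 fell, or 15 and 1 adjusted over the list alone (camera adjusted p 0.00281, adjusted p = 0.909 with an estimated correlation), and the list call ended without mouse 6 (camera adjusted p 0.0694). The stress genes Ddit3 (2.51 ± 0.54) and Atf5 (1.21 ± 0.24) rose. Of 15 integrated stress response genes, 8 rose, and 8 adjusted over the list alone (camera adjusted p 0.00668, adjusted p = 0.909 with an estimated correlation). Of 37 interferon-stimulated genes, 16 fell, and 19 adjusted over the list alone (camera adjusted p 1.01e-05, adjusted p = 0.847 with an estimated correlation). Of 9 MHC class II genes, 6 fell, and 6 adjusted over the list alone (camera adjusted p 0.00148, adjusted p = 0.706 with an estimated correlation), with H2-Aa at -0.97 ± 0.19. Transcripts that dominate in lung amounted to 0.569 to 1.52% of their lung level across the liver libraries, with no baseline subtracted. The highest were 14 d ethanol mice 27 (1.49%) and 28 (1.52%). The 14 d ethanol mice 25 and 26 had 0.62 and 0.57%, and 14 d pair-fed livers 0.69 to 0.75%.

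Of 12 ethanol oxidation genes, 4 fell in liver at 9 h, and 4 adjusted over the list alone (camera adjusted p 0.00845, adjusted p = 0.706 with an estimated correlation). The alcohol dehydrogenase Adh4 fell from 112 ± 33.3 to 31.3 ± 5.59 CPM (edgeR adjusted p 2.18e-06). Catalase, Cat, had -0.35 ± 0.10 (edgeR adjusted p 0.0155) and lost its call without mouse 4 or 8 (edgeR adjusted p 0.0535 and 0.0904). Plin2 had 0.60 ± 0.19 (edgeR adjusted p 0.0243) and lost its call without mouse 1, 4, 6, 8 or 9 (edgeR adjusted p 0.0518, 0.0717, 0.0829, 0.0791 and 0.0723). Dbp fell (-2.63 ± 0.29) and Fkbp5, a glucocorticoid target, rose (1.31 ± 0.33). The other 13 genes reported whatever their result, Cyp2e1, Adh1, Aldh1a1 and Aldh2 among them, did not pass, with log2 fold changes from -0.85 (Cyp7a1) to 0.48 (Marco) and edgeR adjusted p of 0.0594 or above. In all, 3630 of 13752 liver genes changed at 9 h, 1887 higher and 1743 lower, of which 444 and 434 changed at least 2-fold. The diets did not overlap for 31.8% of genes, where chance gives 5.71%. On log2(TPM + 1) the split was 1075 higher and 1888 lower. With only the 7 livers of that time, 2351 genes changed.

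At 24 h the liver of ethanol mice had less desaturase, antigen presentation and cell division transcript and more ribosomal protein and acute phase transcript. Scd1 fell by 3.25 on the log2 scale, with an SE of 0.33 (edgeR adjusted p 2.81e-05; ethanol n = 4, pair-fed n = 3). The elongase Elovl3 (-2.85 ± 0.39) and the desaturase Fads1 (-1.18 ± 0.17) fell too. Of 18 fatty acid synthesis genes, 7 fell, and 14 adjusted over the list alone (camera adjusted p 1.93e-08, adjusted p = 0.225 with an estimated correlation). Of 22 cholesterol synthesis genes, 5 rose, and 10 adjusted over the list alone (camera adjusted p 6.79e-06, adjusted p = 0.396 with an estimated correlation), where 18 had fallen at 9 h. Of 62 cytosolic ribosomal proteins, 30 rose, and 51 adjusted over the list alone (camera adjusted p 4.95e-23, adjusted p = 0.225 with an estimated correlation), by small amounts such as 0.40 ± 0.07 for Rpsa and 0.40 ± 0.08 for Rps18. Of 33 fatty acid oxidation genes, 10 rose, and 13 rose and 2 fell adjusted over the list alone (camera adjusted p 1.4e-07, adjusted p = 0.366 with an estimated correlation), with Hadhb, of the mitochondrial trifunctional protein, at 0.53 ± 0.11. Of 14 heat shock genes, 6 rose, and 6 adjusted over the list alone (camera adjusted p 6.79e-06, adjusted p = 0.225 with an estimated correlation), with the mitochondrial chaperonins Hspe1 (0.83 ± 0.08) and Hspd1 (0.73 ± 0.08).

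Immune transcripts fell in liver at 24 h, and some markers of other cells that are not hepatocytes fell with them. H2-Ab1 went from 42.9 ± 6.34 to 11.8 ± 3.94 CPM (log2 fold change -1.86 ± 0.20, edgeR adjusted p 2.81e-05), and Cd74, the invariant chain, had -1.71 ± 0.19. Of 9 MHC class II genes, 7 fell, and 8 adjusted over the list alone (camera adjusted p 1.64e-10, adjusted p = 0.21 with an estimated correlation). Of 37 interferon-stimulated genes, 18 fell, and 22 adjusted over the list alone (camera adjusted p 1.64e-10, adjusted p = 0.225 with an estimated correlation), with the chemokine Cxcl9 at -1.95 ± 0.32 and Rsad2 at -1.17 ± 0.18. Of 10 Kupffer cell markers, 5 fell, and 7 adjusted over the list alone (camera adjusted p 3.58e-05, adjusted p = 0.225 with an estimated correlation), among them the phosphatidylserine receptor Timd4 (-1.03 ± 0.18). Of 17 monocyte and interstitial macrophage markers, 7 fell, and 8 adjusted over the list alone (camera adjusted p 1.39e-05, adjusted p = 0.307 with an estimated correlation), with Csf1r at -0.86 ± 0.15. Of 21 fibroblast and matrix genes, 2 fell, and 2 adjusted over the list alone (camera adjusted p 0.000961, adjusted p = 0.492 with an estimated correlation), and of 12 hepatic stellate cell markers, 3 fell, and 3 adjusted over the list alone (camera adjusted p 0.00687, adjusted p = 0.396 with an estimated correlation). Both list calls ended without pair-fed mouse 16 (camera adjusted p 0.411 and 0.228). Of 19 hepatocyte markers, 3 rose and 2 fell, among them the secreted protein Ahsg (0.95 ± 0.11). Of 29 cell division genes, 19 fell, and 22 adjusted over the list alone (camera adjusted p 2.06e-10, adjusted p = 0.307 with an estimated correlation), with the mitotic activator Cdc20 at -2.87 ± 0.49 and the kinesin Kif20a at -2.63 ± 0.39.

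Of the acute phase genes in liver at 24 h, 6 of 26 rose and 1 fell, or 15 and 1 adjusted over the list alone (camera adjusted p 4.08e-05, adjusted p = 0.467 with an estimated correlation). Lcn2 (5.38 ± 1.07, edgeR adjusted p 0.00491) and Orm2 (2.81 ± 0.59), uncertain among the Orm copies, were examples. Cyp2b9 rose by 5.78 ± 0.95 on the log2 scale and Cyp2a22 by 3.21 ± 0.62, both uncertain within their families. Of 19 CAR and PXR targets, 9 rose and 2 fell, or 11 and 2 adjusted over the list alone (camera adjusted p 2.06e-05, adjusted p = 0.225 with an estimated correlation). The iron hormone gene Hamp2 (-3.50 ± 0.53), uncertain against its close copy, and the steroid enzyme Cyp17a1 (-2.35 ± 0.48) were among those that fell most. The alcohol dehydrogenase Adh1 rose by 0.77 ± 0.13 (edgeR adjusted p 0.00116). Of 12 ethanol oxidation genes, 4 rose, and 4 adjusted over the list alone (camera adjusted p 0.0266, adjusted p = 0.377 with an estimated correlation), and the list call ended without mouse 10 or 16, with a highest camera adjusted p of 0.105. Aldehyde dehydrogenase Aldh1a1 (0.76 ± 0.21, edgeR adjusted p 0.0239) lost its call without mouse 15 or 16 (edgeR adjusted p 0.0511 and 0.105). The hexokinase Hk2 (-1.03 ± 0.25) lost it without mouse 16 (edgeR adjusted p 0.0775). Fasn (-1.12 ± 0.34) lost it without mouse 10, 12, 13, 14 or 16 (edgeR adjusted p 0.0849, 0.0611, 0.143, 0.0952 and 0.0715). The other 15 genes of that set measured did not pass, with log2 fold changes from -1.24 (Cyp7a1) to 0.51 (Cyp2e1) and edgeR adjusted p of 0.139 or above. In all, 1586 liver genes changed at 24 h, 816 higher and 770 lower, of which 116 and 279 changed at least 2-fold. The diets did not overlap for 21.2% of genes, where chance gives 5.71%. On log2(TPM + 1) the split was 314 higher and 1313 lower. The count was 720 without mouse 16 and 514 with only the 7 livers of that time.

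At 14 d the liver had more transcript of xenobiotic and glutathione enzymes and less of single genes such as Moxd1, Tff3 and Hsd3b5. Cyp2a5 rose by 3.31 ± 0.28 on the log2 scale (edgeR adjusted p 8.51e-06; ethanol n = 4, pair-fed n = 3), and Cyp2b10 went from 1.5 ± 0.45 to 21.8 ± 10.3 CPM (3.87 ± 0.65). Cyp2b9, nearly absent in pair-fed livers at 0.95 ± 0.316 CPM, reached 220 ± 178 CPM (7.86 ± 1.01). These members of the Cyp2a and Cyp2b families are uncertain gene by gene. Of 19 CAR and PXR targets, 13 rose, and 14 adjusted over the list alone (camera adjusted p 2.52e-14, adjusted p = 0.0747 with an estimated correlation). Of 25 NRF2 and glutathione genes, 15 rose, and 18 adjusted over the list alone (camera adjusted p 3.38e-16, adjusted p = 0.0893 with an estimated correlation). The exporter Abcc4 (3.75 ± 0.44), the carbonyl reductase Cbr3 (4.25 ± 0.63) and Nqo1 (1.99 ± 0.19) rose, as did Gsta2 (3.50 ± 0.47), uncertain within its family. Of 14 lipid droplet and lipid uptake genes, 5 rose, and 6 adjusted over the list alone (camera adjusted p 4.14e-06, adjusted p = 0.0893 with an estimated correlation). The fatty acid transporter Cd36 (1.39 ± 0.28) lost its call without mouse 19 (edgeR adjusted p 0.0504), and the lipid droplet protein Cidea (3.15 ± 0.65) without mouse 20 (edgeR adjusted p 0.06). Adipocyte markers moved with this list, which shares Cidea and Plin4 with them: 3 of 6 rose, and 4 adjusted over the list alone (camera adjusted p 0.00757, adjusted p = 0.191 with an estimated correlation). The lung markers Slc34a2 (1.05 ± 0.31) and Col4a4 (1.00 ± 0.30) passed in these livers too, with overlap between the diets. Whether lung transcripts in some liver libraries gave these calls was not tested.

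The monooxygenase-like gene Moxd1 fell from 47.1 ± 44.7 to 0.112 ± 0.0627 CPM in liver at 14 d (log2 fold change -8.65 ± 1.3, edgeR adjusted p 0.000635). Its pair-fed values at 14 d ran from 7.96 to 95.8 CPM. At 9 h Moxd1 was called higher with ethanol in liver (5.38 ± 1.77, edgeR adjusted p 0.0307). The trefoil peptide Tff3 (-6.36 ± 0.97) and Hsd3b5 (-5.25 ± 0.77) fell at 14 d too. So did the complement component C6 (-1.91 ± 0.27) and the urinary proteins Mup7 (-3.15 ± 0.61) and Mup2 (-2.49 ± 0.41), which are uncertain among the Mup copies. Of 19 circadian clock genes, 7 rose and 1 fell, or 11 and 2 adjusted over the list alone (camera adjusted p 9.44e-05, adjusted p = 0.191 with an estimated correlation). Usp2, a clock-controlled protease, rose by 2.90 ± 0.28, the clock repressor Ciart by 2.19 ± 0.33 and the output gene Tef by 0.81 ± 0.09. Adh1 (0.63 ± 0.13) and Aldh1a1 (1.02 ± 0.21) passed and each lost its call without mouse 19 (edgeR adjusted p 0.0517 for both). Fkbp5 (1.26 ± 0.33, edgeR adjusted p 0.0312) lost it without mouse 19, 20, 21, 25, 27 or 28 (edgeR adjusted p 0.16, 0.0821, 0.0735, 0.0568, 0.0737 and 0.0838). The other 17 genes reported whatever their result did not pass, with log2 fold changes from -1.05 (Cyp7a1) to 0.82 (Per1) and edgeR adjusted p of 0.1 or above. Mitochondrially encoded transcripts took 7.69 ± 0.305% of liver counts with ethanol at 14 d and 6.63 ± 0.460% in pair-fed livers. Of 13 such genes, 0 passed in edgeR (camera adjusted p 0.00167, adjusted p = 0.719 with an estimated correlation). Of 21 fibroblast and matrix genes, 1 rose (camera adjusted p 0.0216, adjusted p = 0.726 with an estimated correlation). In all, 868 liver genes changed at 14 d, 500 higher and 368 lower, of which 130 and 105 changed at least 2-fold. The diets did not overlap for 22.6% of genes, where chance gives 5.71%. On log2(TPM + 1) the split was 665 higher and 173 lower. The count was 293 without mouse 19, 331 without 20, 532 without 21, 540 without 25 and 506 without 27, and it was 1991 with voom and 1346 with only the 7 livers of that time.

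**Figure D4:**
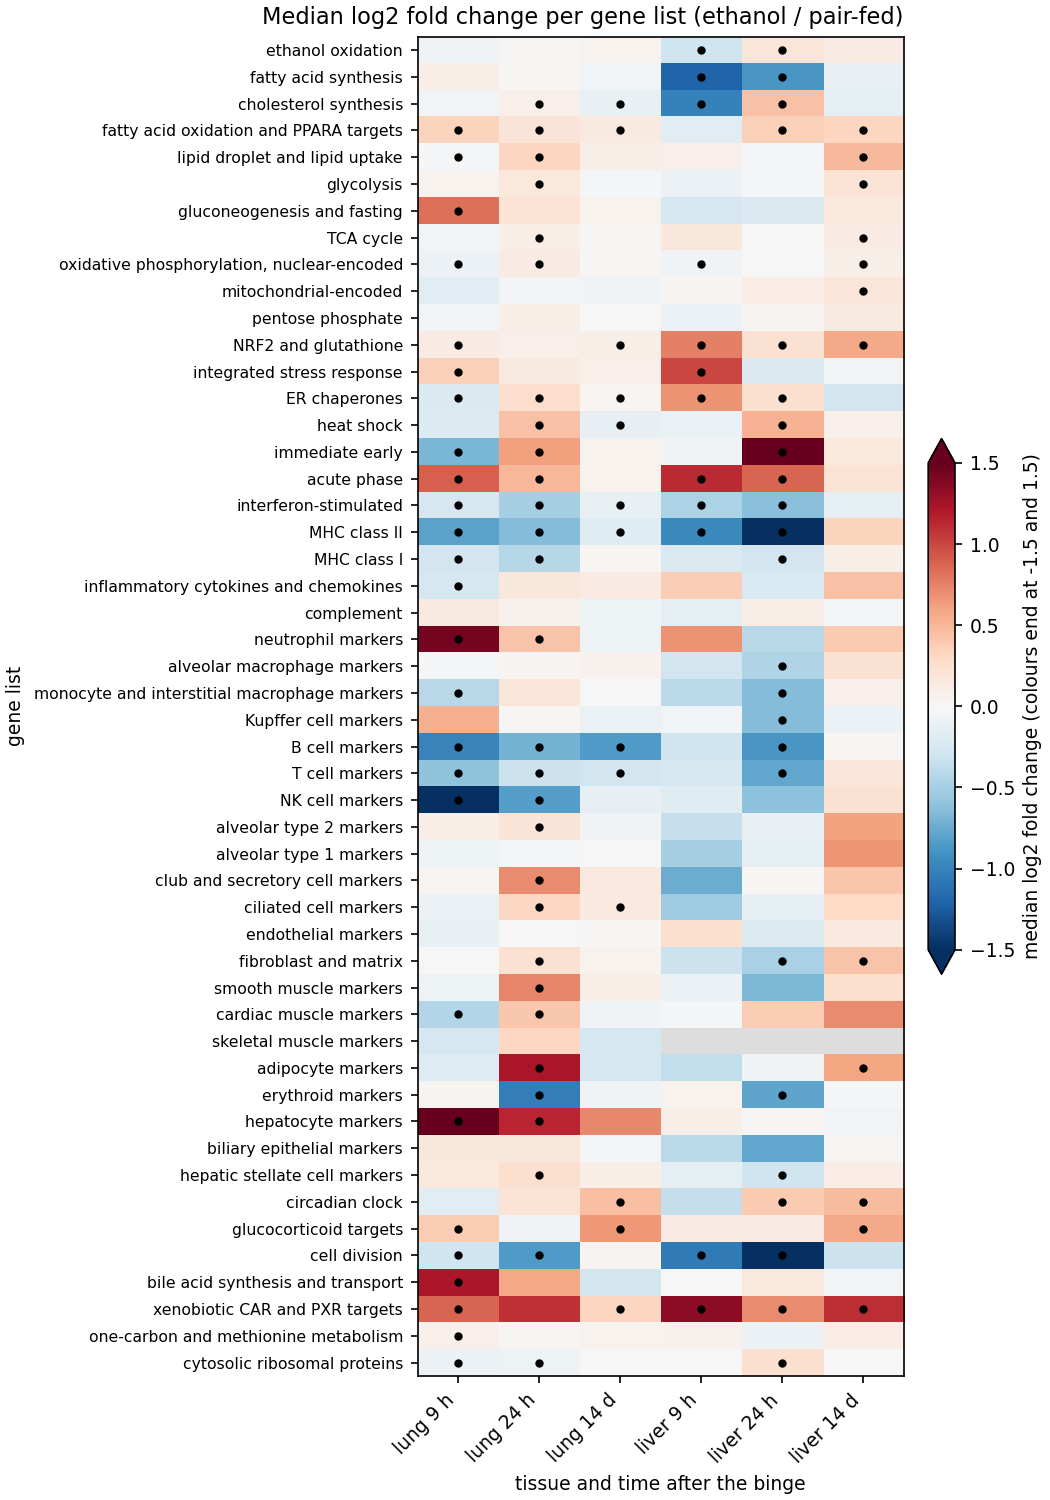
Median log2 fold change (ethanol against pair-fed, colour) of each gene list in 6 comparisons, with a dot where the camera adjusted p with a preset correlation was under 0.05. NK cell markers in lung at 9 h had a median of -1.92 and cell division genes in liver at 24 h of -1.72, both past the end of the colour scale, and grey marks a list with fewer than 5 measured genes.

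The ethanol effect differed among the 3 times for 1231 lung genes and 2783 liver genes in an edgeR test of the diet by time interaction. In lung, the amino acid transporter Slc43a2 went from 1.3 ± 0.11 at 9 h to -0.45 ± 0.10 at 24 h and 0.08 ± 0.10 at 14 d on the log2 scale (edgeR adjusted p 5.28e-06). The integrin Itgb3, of platelets and other cells, had 0.66 ± 0.08, -0.51 ± 0.07 and -0.23 ± 0.07, and the platelet tubulin Tubb1 0.94 ± 0.14, -0.95 ± 0.14 and -0.50 ± 0.13. The tubulin Tuba1b went the other way, with -0.56 ± 0.06, 0.39 ± 0.07 and 0.03 ± 0.06. The receptors Gfra2 and Fgfr4 fell at 9 h (-1.55 ± 0.12 and -1.56 ± 0.13). In liver, the clock output genes Tef and Usp2 were lower at 9 h (-0.84 ± 0.09 and -1.77 ± 0.25) and higher at 24 h (0.45 ± 0.09 and 1.27 ± 0.26) and 14 d (0.81 ± 0.09 and 2.90 ± 0.28), with edgeR adjusted p 4.79e-07 and 3.91e-06. The metabolic regulator Klf15 (-1.17 ± 0.07) and the histone H2az2 (-1.20 ± 0.08) fell at 9 h. Stra6l, a retinol transporter, went from 1.09 ± 0.08 at 9 h to -0.05 ± 0.08 at 24 h and -0.39 ± 0.08 at 14 d (edgeR adjusted p 4.79e-07).

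Pair-fed mice also differed among the times, for 1426 genes in lung and 698 in liver by the same test. Usp2 averaged 60.2 CPM in pair-fed livers at 9 h, 15.8 at 24 h and 7.63 at 14 d (edgeR adjusted p 6.63e-05), and Tef averaged 557 CPM, 280 and 205 in pair-fed lungs (edgeR adjusted p 1.16e-05). The integrin Itgb6 averaged 20.2 CPM in pair-fed lungs at 9 h, 38.6 at 24 h and 51.3 at 14 d (edgeR adjusted p 9.97e-07). The lung count was 853 without mouse 8, 350 without mouse 9 and 919 without mouse 19. The liver count was 254 without mouse 8, 208 without 9, 457 without 16, 385 without 19, 324 without 20 and 382 without 21, and it was 1316 with DESeq2, 2258 with voom and 1412 on log2(TPM + 1).

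The ethanol effect differed between liver and lung for 2787 of 13355 genes at 9 h, 950 at 24 h and 332 at 14 d. At 9 h Cyp2b10 rose far more in liver than in lung (6.99 against 0.62 on the log2 scale, difference 6.37 ± 0.55, edgeR adjusted p 4.02e-09). The endothelial lipase Lipg fell in liver and rose in lung (-2.77 and 0.67, difference -3.44 ± 0.31, edgeR adjusted p 4.57e-09), and Slc43a2 (-0.40 and 1.3) and the mitochondrial carrier Slc25a13 (-0.77 and 0.80) did so too. The growth factor receptor Tgfbr2 rose in liver (1.37), with -0.01 in lung. At 24 h Scd1 fell in liver (-3.25), with 0.05 in lung (difference -3.31 ± 0.38, edgeR adjusted p 3.85e-06), and complement Hc rose in liver (0.49) and fell in lung (-0.76). The lipid transfer protein Pltp had -2.19 in liver and -0.05 in lung, and properdin, Cfp, -1.08 and 0.29. At 14 d the exporters Abcc4 (3.75 in liver, -0.20 in lung, difference 3.94 ± 0.43, edgeR adjusted p 1.43e-06) and Abcb1a (2.05 and -0.14) were among the genes of smallest p, with the glutathione transferase Mgst3 (1.66 and 0.05), the dehydrogenase Idh2 (1.05 and 0.10) and complement C6 (-1.91 and 0.05).

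The differences between liver and lung split into 1427 positive and 1360 negative at 9 h, 432 and 518 at 24 h, and 198 and 134 at 14 d. On log2(TPM + 1) these splits were 747 and 1469, 155 and 633, and 321 and 59. With only the 14 libraries of each time the counts were 1560, 518 and 808. The 24 h count was 583 without mouse 10, 546 without 14 and 255 without 16. The 14 d count was 94 without mouse 19, 81 without 20, 189 without 21, 205 without 25, 182 without 27 and 210 without 28, and it was 588 with DESeq2 and 1248 with voom.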

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

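The choice of which genes to look at for single far-off mice followed from the results, while the tests of differences between times and tissues were fixed at the start. Of 275 groups of 4 ethanol libraries, 23 had a mouse far from the other 3, where chance flags about 1 in 20 groups of normal, independent values. Genes of the same libraries are not independent, so the 23 cannot be judged against that rate. Pair-fed groups, with 3 mice each, were not checked. Among the 23, liver at 14 d had 4 in mouse 25, all of them high, and liver at 24 h had 3 in mouse 14. No explanation of them was tested.

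In lung at 9 h, the collagenase Mmp8 was at 186.2 CPM in mouse 6 against 10.51 to 27.11 in the other ethanol mice. The retinoic acid hydroxylase Cyp26b1 was at 1530 CPM in mouse 4 against 233.3 to 340.8. The platelet tubulin Tubb1 was at 13.6 CPM in mouse 5 against 16.25 to 16.75. In lung at 24 h, the dendritic cell lectin Siglech was at 2.661 CPM in mouse 14 against 1.691 to 1.822, and Mki67 at 5.967 CPM in mouse 10 against 7.914 to 8.108. Mouse 11 had Pltp at 560.2 CPM against 637.8 to 641.5 and the desaturase-like Fads3 at 157.5 against 142.9 to 143.5. In lung at 14 d, Slc43a2 was at 151.0 CPM in mouse 26 against 166.8 to 169.6, and Fgfr4 at 49.43 CPM in mouse 27 against 58.58 to 58.86.

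In liver at 9 h, mouse 6 had Hsd3b5 at 1.525 CPM against 2.332 to 2.451, Fasn at 1012 against 529.5 to 594.6, and a mitochondrial share of 6.07% against 6.59 to 6.68%. Ddit3 was at 60.38 CPM in mouse 4 against 11.16 to 16.31, and Slc25a13 at 222.5 CPM in mouse 5 against 191.7 to 195.3. In liver at 24 h, mouse 14 had Orm2 at 85.29 CPM against 22.59 to 31.99, Lcn2 at 886.0 against 139.8 to 244.1, and Cyp2b9 at 122.4 against 24.42 to 39.19. In liver at 14 d, mouse 26 had Tff3 at 0.04254 CPM against 0.1446 to 0.1558 and Cyp2b10 at 6.381 against 25.75 to 27.77. Mouse 25 had Cyp2a22 at 98.06 CPM against 28.08 to 38.79, Cyp2a4 at 33.99 against 3.245 to 6.594, Cyp2b13 at 38.38 against 2.727 to 8.087, and Abcc4 at 53.85 against 27.26 to 30.81.

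Differences between groups were found by edgeR tests of the interaction itself. The ethanol effect differed among times for 1231 lung genes such as Slc43a2 and 2783 liver genes such as Tef, and between liver and lung for 2787 genes at 9 h, 950 at 24 h and 332 at 14 d, such as Cyp2b10, Scd1 and Abcc4.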

How the results depend on the processing

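Of the values below, those with the liver share subtracted and without mice 4 and 5 come from tests chosen after the results were seen. Counts moved by over 1.5 times as follows, against the edgeR values given earlier, and the cause was not tested. With DESeq2, 82 lung genes changed at 14 d, 1316 differed among pair-fed livers and 588 between tissues at 14 d. With voom, lung counts were 1488 at 9 h, 1333 at 24 h and 202 at 14 d, liver counts 1991 at 14 d and 2258 among pair-fed livers, and the tissue difference at 14 d 1248. On log2(TPM + 1), lung had 483 genes at 24 h and 1 at 14 d, and pair-fed livers 1412. With only the 7 libraries of a time, lung had 768 genes at 9 h and 135 at 14 d, and liver 2351, 514 and 1346 at 9 h, 24 h and 14 d. These fits take the spread from that time alone. In both tissues their count was below that of the shared fit at 9 h and above it at 14 d. With only the 14 libraries of a time, the tissues differed for 1560, 518 and 808 genes. Without mice 4 and 5, 1561 lung genes changed at 9 h, of which 1340 were among the 2671 with all mice.

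With each mouse left out in turn, lung counts ran from 1474 to 2773 at 9 h, 192 to 871 at 24 h and 0 to 23 at 14 d, where 1532 genes have an unadjusted edgeR p under 0.05. Liver counts ran from 2556 to 3587, 720 to 1591 and 293 to 893. Counts among times ran from 834 to 1371 in lung and 2103 to 2909 in liver, among pair-fed lungs from 350 to 1884, and among pair-fed livers from 208 to 937. The tissues differed for 2007 to 2812, 255 to 841 and 81 to 426 genes. The mouse numbers pair lung and liver, and with the mouse as a replicate block the tissues differed for 2539 genes at 9 h, 770 at 24 h and 296 at 14 d. The block was run for these 3 differences only, as each mouse gives 1 library per tissue.

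Camera called 116 lists, 1 with an estimated correlation and 111 to 125 with a mouse left out, and fry called 63. Of 511 results for named genes past the threshold, 324 held with any mouse left out, 503 with DESeq2, 508 with RLE scaling and 449 on log2(TPM + 1). Among the 503, 6 had no adjusted p from DESeq2 and were counted by direction alone. With the liver share subtracted, 190 of 196 results for named lung genes held, pooled over the times. Another 6, all at 9 h, fell below the low-count filter and are not among the 196. Before that filter, 129 results were at 9 h, 71 at 24 h and 2 at 14 d. The share was at most 0.152% at 24 h and 0.00417% at 14 d, where little was subtracted. The pooled count therefore does not measure how well the 9 h calls held. The complement gene C8a turned from 1.47 to -0.86 in lung at 9 h with the share subtracted, and passed the threshold before but not after it. RLE scaling, no filter, the filter of CPM 1 in 3 libraries and the legacy fit moved no count of changed genes by over 1.5 times. At a depth of 14.6 M counts and up, recovery of simulated 1.5-fold changes was 14.9 to 24.2% at an assumed dispersion of 0.03. Genes of small spread can pass at such folds, such as Tap1 in lung at 24 h (-0.55 ± 0.09). The simulation changed only 200 genes per comparison, so its recovery need not hold for the real data.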

Other observations

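The platelet and sex-biased lists, and all tests of clock, sex-biased and hepatocyte transcripts except the match of lungs to their own livers, were chosen after the results were seen, while the splits were fixed at the start. Several platelet transcripts in ethanol lungs were higher at 9 h and lower at 24 h. Of 22 platelet and megakaryocyte markers, 11 rose and 1 fell at 9 h, 9 fell at 24 h and 1 fell at 14 d. The list holds Ppbp, Itgb3 and Tubb1, which prompted it, so its counts are a description and no test of the pattern. The glycoprotein subunit Gp1ba went from 1.09 ± 0.17 at 9 h to -1.0 ± 0.17 at 24 h, while the chemokine Pf4 fell at 9 h (-0.49 ± 0.13). In liver, 173 genes were higher at both 24 h and 14 d where independent lists of these sizes would share 29.7, and 95 were lower at both where they would share 20.6. The animals and controls of these times differ. Lung and liver shared 295 higher and 242 lower genes at 9 h where independent lists would share 166 and 143. These tissues come from the same mice, so the values from independent lists leave out effects that a mouse or its hour of sampling has on both, and the overlap was not recomputed without liver transcripts in the lungs.

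Sex-biased liver genes shifted at 14 d toward the female pattern. Of 27 male-biased genes, 14 fell, and of 21 female-biased genes, 9 rose, so that 23 of 23 called genes lay on the side of the female pattern, in lists that include the genes that prompted them. Earlier times were mixed. At 9 h, 4 male-biased genes were higher, Moxd1 among them, and 5 lower, and at 24 h 1 was higher and 4 lower. Female-biased genes numbered 7 higher and 1 lower at 9 h and 5 higher and 2 lower at 24 h. The pattern was not limited to the Mup and Cyp2 families. Outside them 13 of 13 called genes lay on that side, such as the transcription factor Tox (1.27 ± 0.26) and the complement gene C6 (-1.91 ± 0.27). Genes such as C6, Moxd1 and Hsd3b5 were known calls when the lists were written, and others, such as Cyp4a12b, have close copies of their own. The count therefore describes these genes and cannot decide whether shared reads played a part. Animals of the other sex in a group are argued against, since the lowest median ratio of 4 Y-linked genes to the mean of the livers was 0.803. That test first took each gene alone, where the lowest ratio was 0.393, short of the 0.5 first required, and was changed to the median after this was seen. No biological explanation was tested.

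Hepatocyte transcripts in the 9 h lungs were highest in mice 4 and 5. RNA of the same animals' livers is argued against as the cause, since over liver-dominant genes the lung log2 fold change rose with that of liver with a slope of only 0.098 (SE 0.036). Whether reads passed between pooled libraries cannot be told from the match of lungs to their own livers. Only 1 of 7 lungs resembled the liver of its own mouse most among the 9 h livers. The best r of each lung was only 0.0614 to 0.214, and random matching would give such a count. Reads of one liver library could explain the transcripts, since all 7 lungs resembled one and the same liver library most, that of ethanol mouse 15 at 24 h. Over 135 genes, which are not independent replicates, the mean of all livers came close (r 0.926 against 0.936 for mouse 6) and was the better match for mouse 9 (0.909 against 0.9), so that library matched better than the mean in 6 of 7. Reads passed between libraries and reads of one liver library are accounts that overlap. A further test, of a higher liver share with ethanol, was dropped from the set after its exact two-sided permutation p of 0.257 was seen. Whether the libraries were pooled is not given in the sources used here.

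Clock transcripts moved in liver, at 9 h down for Dbp (-2.63 ± 0.29) and up for the opposite-phase genes Arntl (1.59 ± 0.38) and Clock (0.77 ± 0.13), and at 14 d up for Usp2 and Tef. Some moved in lung too at 9 h, such as Arntl (1.14 ± 0.28) and Nr1d2 (-0.60 ± 0.14, whose call ended without mouse 1 at an edgeR adjusted p of 0.0527), and 16 of 19 had the same direction in both tissues at 9 h and 16 of 19 at 14 d, as different hours would also give. If ethanol and pair-fed mice had been taken at different hours, lung and liver of the same mice would be expected to shift together, and the slope of lung on liver over 19 clock genes was 0.323 (SE 0.0743) at 9 h and 0.378 (SE 0.121) at 14 d. The limit first set, a slope plus 2 SE under 0.5, was met at 9 h and not at 14 d, which would have argued against different hours at 9 h; it was lowered to 0 after the values were seen, because 0.5 assumed that both tissues shift alike. Different hours and an effect of ethanol on the clock cannot be told apart, because the hour of sampling is not given in the sources used here and tissues need not shift by equal amounts.

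Splits of the same mice into other groups show how often a regrouping calls as many genes as the real one. For lung at 14 d chance remains an explanation, since 2 of 35 splits called as many genes as the real one. There were 2 genes in the real split and 12 in the highest other. Whether a structure among those mice other than diet lies behind the 12 was not tested. In the other tests of diet the real split alone, 1 of 35, reached its count. That is the fewest that 35 splits allow, and the number of such tests was not corrected for. Chance is thus less likely there but not excluded. The real and highest other counts were 2671 and 1630 for lung at 9 h, 874 and 196 for lung at 24 h, 3630 and 2159 for liver at 9 h, 1586 and 351 for liver at 24 h, and 868 and 338 for liver at 14 d. For the difference between tissues they were 2787 and 1622 at 9 h, 950 and 190 at 24 h, and 332 and 172 at 14 d. Among times, 100 splits were compared, the real one and others drawn at random, not all that are possible. The real one alone, 1 of 100, reached its count. The counts were 1231 against 319 in lung, 2783 against 901 in liver, 1426 against 1252 among pair-fed lungs and 698 against 326 among pair-fed livers.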
